A study of Mus musculus with 6 samples.

How the data were processed

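Gene expression was measured on 6 single-colour Illumina BeadChips, each hybridised with biotin-labelled cRNA from total RNA of 1 culture of mouse hematopoietic stem and progenitor cells. The groups, taken from the sample titles, were 3 control cultures and 3 cultures with 1 mM valproic acid (VPA), all of 24 h. The series design describes the replicates as independent and biological. The replicate numbers of the 2 groups are treated as names only, since nothing in the labels ties a numbered control to the VPA culture of the same number.

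The deposited table of the whole series holds, per the file headers, the raw mean signal intensity of each of 25697 probes on each array and a detection p-value for it, the share of negative control beads at or above that signal. GenomeStudio is named in the submitters' processing notes without a version. The intensities were not background subtracted or normalized, judged from the header and from their values. A second deposited table holds log2 values of the same arrays. Its columns all had a median of 6.94 and followed the rank order of the raw signals of the same array. Quantile normalization would give both, but these values alone do not show that it was used. On probes with bright signals its slope on the log2 raw signal ranged from 0.958 to 1.08. What was done to the low signals, and which arrays set any common distribution, stay unknown. This table was used only as an alternative.

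Signals were background corrected and normalized in limma 3.58.1 under R 4.3.3 with neqc, which infers the negative controls from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Background subtraction widens the log2 changes of dim probes against uncorrected values. Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept, 11115 probes or 43.3% of the array. Probe names came from the GEO platform annotation, which lists 1 gene symbol for 23978 probes, several for 0 and none for 1719. Looked up by Entrez gene identifier in the RefSeq gene table of assembly GRCm38.p6, 0 symbols had to be changed. The kept probes covered 7967 named genes and 640 unnamed probes. A gene is shown by its probe with the highest mean over all 6 arrays, and 1924 genes had more than 1 kept probe. Ly6a, which encodes Sca-1, and Kit, the genes of the surface markers used in the sort, were not analysed here. No genome sequence or probe positions were used, so no coordinates are given.

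VPA was compared with control by lmFit and eBayes over the kept probes, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Errors are standard errors (SE) of the log2 change from this fit, or standard deviations (SD) of normalized log2 values, with n = 3 arrays per group. A probe without detection on any array of a group has only a bound there. Its fold is given as "at least", the mean of the group with detection against the mean, per array, of the higher of the lowest detected signal and the probe's own signal. With 6 arrays, the number of arrays limits the precision, and a two-sided exact permutation test of a single gene, 3 against 3, cannot go below 0.1.

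The choices above, 24 gene lists holding 773 genes, the rule for named genes and most alternatives were fixed before the data were examined. Of the lists, 23 were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and 1, of sex-linked genes, served as a sample check. Named genes are the 10 with the largest rise and the 10 with the largest fall among genes past the threshold that were detected on at least 1 array of each group and whose groups did not overlap. To these come up to 5 genes in each direction detected on all arrays of one group and none of the other, and from each list up to 4 members past the threshold, or the 2 with the largest change where none passed. Clone, LOC, Gm and RIKEN identifiers were passed over among the genes outside the lists.

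The alternatives were other background corrections, median scaling, the deposited log2 values, other detection filters, another variance model, array weights, a block on the replicate number, each array left out in turn, stricter thresholds, the mean of a gene's probes, camera with an estimated correlation and the rotation test fry. A further 2 were chosen after seeing the data, a normalization of 5 arrays without VPA replicate 1 and a covariate from Actb probes.

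The procedure was tested on simulated signals of the VPA and control arrays, built from the measured backgrounds, means and spreads, with 200 genes changed. Over the 11131 probes it kept, it recovered 1 of 81 genes changed 1.5-fold, 25 of 60 changed 2-fold and 39 of 59 changed 4-fold, and called 1 probe that had not been changed. A list shifted by 0.5 on the log2 scale was recovered, with 0 of the other lists called by camera. Noise was drawn independently for each probe, with the same spread for a probe on every array. The simulation thus does not test list calls under correlation between genes, nor the wider spread of VPA replicate 1.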

Results

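The study followed gene expression in hematopoietic stem and progenitor cells of C57Bl/6 mice, isolated from bone marrow by the L-S+K+ phenotype, that is, without lineage markers and with Sca-1 and Kit on their surface. The cells were kept for 24 h in medium with serum, stem cell factor and granulocyte/macrophage colony-stimulating factor. To 3 cultures 1 mM VPA was added, a short-chain fatty acid that inhibits histone deacetylases, and 3 control cultures received the growth factors alone. The question was which transcripts respond to the inhibitor within the first day, with Sca-1 as the gene the series is named for. Its gene, Ly6a, was not analysed here, and the comparison covers the 7967 other genes measured.

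On 5 of the 6 arrays the median raw signal of the kept probes lay between 456 and 647, which was 4.25 to 5.27 times the median signal of undetected probes. VPA replicate 1 was dimmer, with a median of 226, or 2.46 times its background. Its normalized values correlated with those of VPA replicates 2 and 3 at r = 0.957 and r = 0.947 across probes, while pairs of controls reached at least 0.989 and VPA replicates 2 and 3 0.991. On this array 243 probes were detected that were not detected on any other. Between 10846 and 11439 probes were detected per array. The median SD between replicates was 0.13 on the log2 scale in the control group and 0.28 in the VPA group, each over 3 arrays. Between VPA replicates 2 and 3 it was 0.11, but over 2 arrays, so it does not compare directly with 0.13. The SD across probes of the log2 difference was 0.29 for that pair and 0.28 to 0.33 for pairs of controls.

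**Figure D1:**
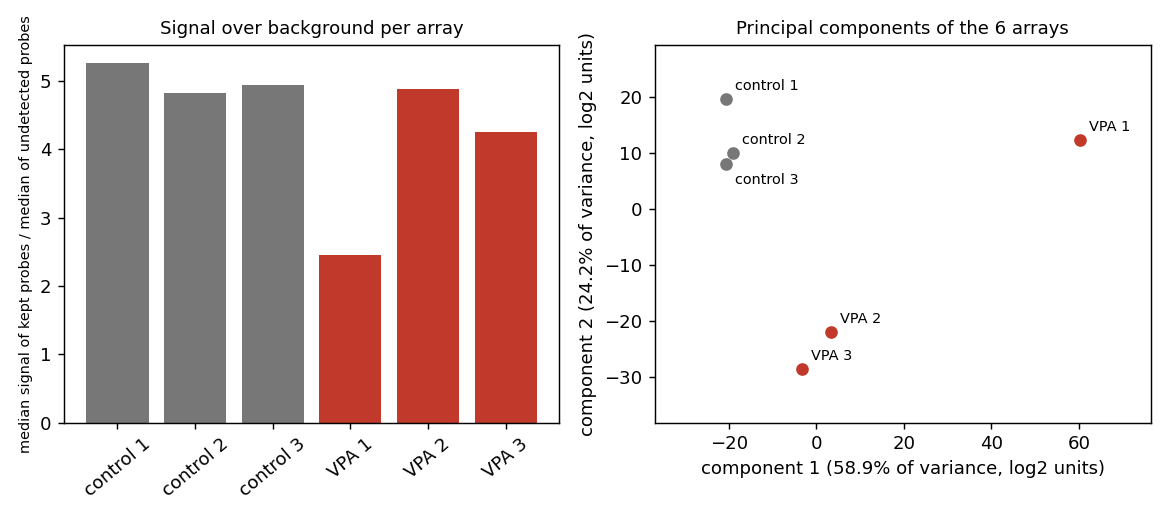
Left, median raw signal of the kept probes divided by that of undetected probes, 1 bar per array; right, the first 2 principal components of the normalized log2 values, 1 point per array, grey for control and red for VPA. VPA replicate 1, at 2.46 times its background, lies apart from the other arrays along component 1, which holds 58.9% of the variance, and VPA replicates 2 and 3 part from the controls along component 2.

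With VPA the largest rise was that of Ckb, the brain-type creatine kinase, which was 16-fold higher (log2 change 4.0 ± 0.25 SE, n = 3 per group). Gpc3, a glypican of the cell surface detected on 1 of 3 control arrays, rose 15-fold (3.91 ± 0.26). Fscn1, the actin-bundling protein fascin, rose 10.4-fold (3.38 ± 0.25) and Thy1, a surface glycoprotein found on mouse stem cells and T cells, 9.26-fold (3.21 ± 0.21). The next were Cox4i2, an isoform of a cytochrome c oxidase subunit, at 7.58-fold, Tceal5 at 7.51-fold, the guanine nucleotide exchange factor Arhgef25 at 6.54-fold and the small GTPase Rab34, detected on 2 of 3 control arrays, at 6.51-fold. They were followed by protein kinase C beta (Prkcb) at 6.34-fold and carbonyl reductase 3 (Cbr3) at 5.97-fold. The largest falls were smaller. Dntt, the terminal deoxynucleotidyl transferase of lymphoid precursors, was 4.97-fold lower (log2 change -2.31 ± 0.25) and was detected on 1 of 3 VPA arrays. Cox6a2, the muscle isoform of another cytochrome c oxidase subunit, was 4.94-fold lower (-2.30 ± 0.23).

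Rapsn, which clusters acetylcholine receptors at the neuromuscular junction, was 3.60-fold lower with VPA, the mannose receptor Mrc1 3.15-fold and the mast cell carboxypeptidase Cpa3 2.91-fold, the last 2 with detection on 2 of 3 VPA arrays. Bex6 fell by 1.32 on the log2 scale, the integrin subunit Itgb6 by 1.30, Fbxw4 by 1.27, Havcr2, which encodes the receptor Tim-3, by 1.25 and Dhrs4 by 1.07. All 20 genes had adjusted p between 0.000996 (Ckb) and 0.0248 (Fbxw4) by limma. By the rule that picked them, each passed the threshold with its 3 VPA arrays on one side of the 3 control arrays. The calls of the 10 rises held in each of the 17 alternatives that gave them a value. Of the 10 falls, those of Dntt, Cox6a2 and Rapsn held, and 7 ended when 1 of the control arrays was left out, with adjusted p up to 0.128 (Fbxw4 without control replicate 2). The sizes depend on the background correction, since without it the log2 rise of Gpc3 was 2.37 and that of Ckb 3.04. A second probe of Arhgef25 gave a log2 change of -0.02 (adjusted p = 0.976) and one of Cbr3 1.12 (adjusted p = 0.0968), whereas the further probes of Gpc3, Rab34, Rapsn, Cpa3, Itgb6 and Havcr2 passed in the same direction.

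**Figure D2:**
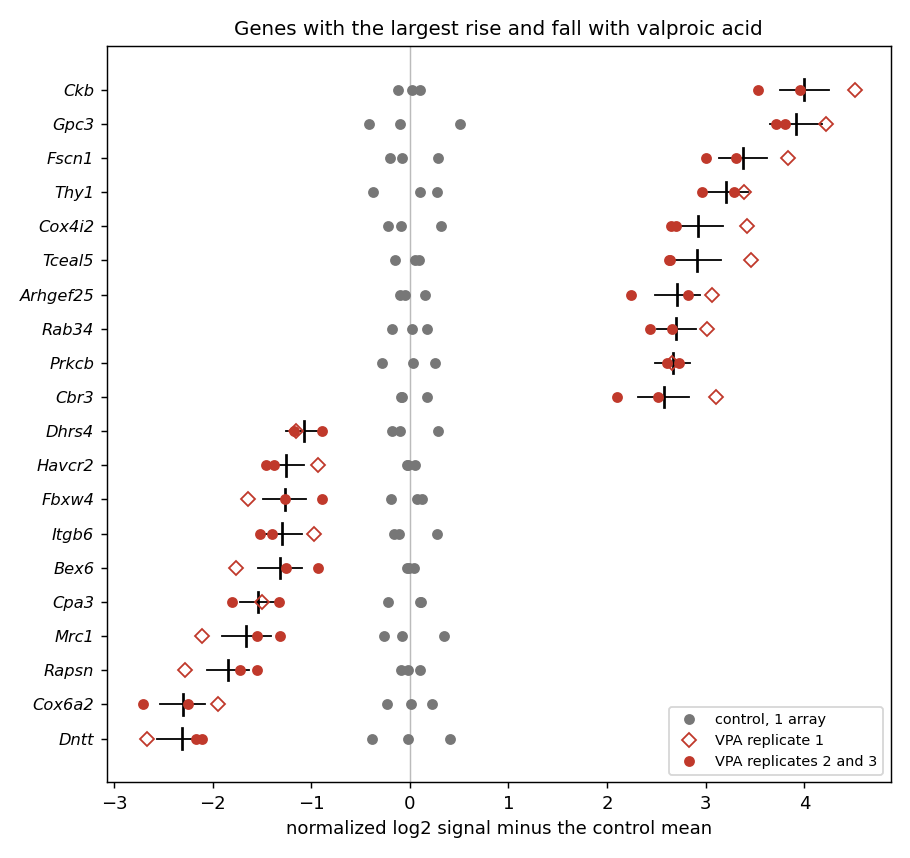
Normalized log2 signal of each array minus the mean of the 3 control arrays for the 10 genes with the largest rise and the 10 with the largest fall; black bars mark the fitted log2 change ± SE, grey points controls, open diamonds VPA replicate 1 and red points VPA replicates 2 and 3. By the rule that picked these genes, the VPA arrays lie on one side of the controls in each. The fitted changes run from 4.0 for Ckb to -2.31 for Dntt.

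Some genes were detected in a single group. Fbxo2, an F-box protein that binds glycoproteins, was detected on all 3 VPA arrays and on 0 of the control arrays and was at least 9.50-fold higher with VPA (adjusted p = 0.000996). Crip2 was at least 6.73-fold higher, Flt1, a receptor of vascular endothelial growth factor, at least 4.72-fold, tescalcin (Tesc) at least 4.32-fold and Echdc2 at least 3.97-fold. In the other direction, Il7r, the interleukin 7 receptor chain that lymphoid precursors need, was detected on all control arrays and on 0 of the VPA arrays and was at least 2.99-fold lower with VPA (adjusted p = 0.00108). Klhl30 was at least 1.84-fold lower, Smg8 at least 1.68-fold, Tmem178 at least 1.40-fold and Wfdc18 at least 1.19-fold. The calls of Smg8, Tmem178 and Wfdc18 ended in several alternatives, without background correction among them (adjusted p up to 0.207 for Wfdc18). A second probe of Smg8 gave an adjusted p of 0.763. The call of Flt1 ended without control replicate 1 (adjusted p = 0.0573).

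Over all genes, 272 were higher and 25 lower with VPA by limma at adjusted p 0.05, or 324 and 48 probes. At least 2-fold changes made up 212 of the rises and 15 of the falls, and at least 4-fold changes 35 and 2. In 2219 genes, 27.9%, the groups did not overlap, where chance gives 10%. Without the dim array, VPA replicate 1, 494 genes were higher and 127 lower, and these included all 272 and all 25. With that array left out of the normalization too, 382 were higher and 104 lower, including 208 of the 272 and all 25. The counts fell when any 1 of the arrays other than VPA replicate 1 was left out. They were 54 and 5 without control replicate 1, 74 and 8 without control replicate 2 and 73 and 5 without control replicate 3. All genes called without control replicate 1, or without control replicate 3, were among the 272 and 25. Without VPA replicate 2 the counts were 124 and 12, and without VPA replicate 3 192 and 16. Whether fewer arrays or particular ones lowered them was not tested. With median scaling in place of quantile normalization 176 genes were higher and 17 lower, and with array weights 1365 and 1128. Of 79 genes with several probes and a call, 58 had at least 1 probe that did not pass, and 0 had probes called in opposite directions.

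Of 11 measured lymphoid genes Dntt and Il7r fell with VPA, or 3 genes when adjusted over the list alone. The list was lower as a whole by camera (adjusted p = 0.0202; median log2 change -0.34, or -0.15 without VPA replicate 1). That call was lost with an estimated correlation (adjusted p = 0.278 with an estimated correlation). The estimate was 0.0097, not above the preset 0.01, so a higher correlation does not account for that loss. The call also ended with the stricter detection filter (0.0837), with array weights (0.0608) and with VPA replicate 1 left out of the normalization too (0.0642). Its adjusted p ranged from 0.00965 to 0.278 by camera. Genes of neutrophils and their primary granules were also lower as a list (adjusted p = 0.0395, median -0.38). With an estimated correlation, of 0.641 here, they were not (adjusted p = 0.579 with an estimated correlation). By limma 0 of 22 passed singly over all genes, against 1 higher and 7 lower at an unadjusted p under 0.05 and 1 higher and 4 lower when adjusted over the list alone. The largest differences were those of the antimicrobial peptide gene Camp (log2 change -1.37 ± 0.38, adjusted p = 0.119) and Chil3 (-1.36 ± 0.30, adjusted p = 0.0616). The neutrophil call also ended without control replicate 3 (adjusted p = 0.147), without VPA replicate 3 (0.316) and with median scaling (0.145). Array weights (0.854), the mean of a gene's probes (0.0616) and fry (0.438) ended it too, over a range of 0.000174 to 0.854. Without VPA replicate 1 the adjusted p was 0.0484. It was 0.0642 with that array left out of the normalization too, and 0.627 without that array with an estimated correlation.

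Of 24 genes of hematopoietic stem cells, Thy1 and the cell cycle inhibitor Cdkn1c (3.19-fold) rose, likewise when adjusted over the list alone. The list missed the threshold (adjusted p = 0.0804) but passed without VPA replicate 1 (0.0484) and with the stricter detection filter (0.0121), over a range of 0.0121 to 0.279 by camera. It did not pass with that array left out of the normalization too (0.0642), nor without it with an estimated correlation (adjusted p = 0.359 with an estimated correlation). Of 12 genes of mast cells, basophils and eosinophils Cpa3 fell, and 2 rose and 3 fell when adjusted over the list alone (list adjusted p = 0.119). Of 19 genes of monocytes, macrophages and dendritic cells Mrc1 fell and Batf3, a transcription factor of dendritic cells, rose at least 1.26-fold, the same numbers when adjusted over the list alone (0.319). Of 16 erythroid genes biliverdin reductase B (Blvrb, 2.12-fold) and the erythropoietin receptor (Epor, at least 1.45-fold) rose, 2 also when adjusted over the list alone (0.309). Of 16 genes of megakaryocytes and platelets Alox12 rose at least 1.41-fold, 1 gene also when adjusted over the list alone (0.565). Of 8 endothelial and stromal genes 0 passed over all genes and 1 did so upward when adjusted over the list alone and at an unadjusted p under 0.05. Emcn, at a log2 change of 0.87 ± 0.19, had an adjusted p of 0.0580 and Plvap, at 0.65 ± 0.28, one of 0.302 (list 0.447). Plvap was at 0.41 without VPA replicate 1 and 0.42 without control replicate 2. Of 5 measured members of the Ly6 family, to which Ly6a belongs, 0 passed by limma in any of these counts and 2 were higher at an unadjusted p under 0.05, Lynx1 (log2 change 0.72 ± 0.22) and Ly6e. The log2 change of Ly6d, -0.62 ± 0.30, was not past that value either (list 0.319), and was -0.32 without VPA replicate 3.

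Genes of DNA replication and the G1/S transition were lower as a list with VPA (adjusted p = 0.0475 by camera). With an estimated correlation they were not (adjusted p = 0.278 with an estimated correlation), though the estimate, -0.0044, was below the preset 0.01. The median log2 change was -0.20, or -0.07 without VPA replicate 1. By limma 0 of 31 passed singly or when adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. Of members not past that value, Mcm3, a subunit of the replicative helicase, had a log2 change of -0.66 ± 0.37 and the DNA ligase Lig1 one of -0.61 ± 0.27. Mcm3 ranged from -0.37 without control replicate 1 to -1.01 without control replicate 3, and Lig1 was at -0.30 without VPA replicate 1. The list's call was also lost without control replicate 2 (0.0621), control replicate 3 (0.0559), VPA replicate 1 (0.112) or VPA replicate 2 (0.0512). Median scaling (0.401), array weights (0.0863), VPA replicate 1 left out of the normalization too (0.131) and the mean of a gene's probes (0.0701) also ended it. So did fry (0.0815), and the range was 0.0176 to 0.401. Of 20 cyclin-dependent kinase inhibitors and p53 targets, Cdkn1c, the stress gene Gadd45g (3.02-fold), Zmat3 (2.69-fold) and the death receptor gene Fas (at least 1.64-fold) rose, 5 genes when adjusted over the list alone. As a list they missed the threshold (adjusted p = 0.0755) and passed without VPA replicate 1 (0.0484) and with array weights (0.0481), over a range of 0.0481 to 0.278 by camera. They did not pass with that array left out of the normalization too (0.0704), nor without it with an estimated correlation (adjusted p = 0.334 with an estimated correlation). Of 28 mitosis genes 0 passed over all genes or over the list alone, and 1 was lower at an unadjusted p under 0.05. The spindle genes Tpx2 and Ndc80, not past that value, had log2 changes of -0.63 ± 0.34 and -0.57 ± 0.25 (list 0.581). Without VPA replicate 1 these were -0.21 and -0.30. Of 34 genes of ribosome biogenesis and MYC targets 0 passed over all genes or over the list alone and 2 were lower at an unadjusted p under 0.05, with Pa2g4 at -0.80 ± 0.21 and Nop56 at -0.80 ± 0.33. Their list missed the threshold (0.0567; adjusted p = 0.302 with an estimated correlation). It passed in 7 of 19 alternatives, among them without control replicate 2 (0.0325) and in the deposited values (0.0326), over a range of 0.0325 to 0.673. Without control replicate 1 the log2 change of Nop56 was -0.47. Of 13 members of the BCL2 family Bik rose at least 1.19-fold, 1 gene also when adjusted over the list alone. The list's median was -0.05, its mean 0.09 and its test upward (0.857). Of 20 heat shock and unfolded protein genes 0 passed over all genes or over the list alone, and 1 was higher and 2 lower at an unadjusted p under 0.05, Atf4 among the latter at -0.87 ± 0.30. Dnaja1, at -0.56 ± 0.28, was not past that value (list 0.119). Dnaja1 was at -0.24 without VPA replicate 1 and Atf4 at -0.51 without control replicate 1.

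Neuronal genes were higher as a list with VPA (adjusted p = 0.0202; median log2 change 0.27, or 0.26 with genes detected in a single group at their bounds). With an estimated correlation they were not (adjusted p = 0.278 with an estimated correlation), though the estimate, -0.0045, was below the preset 0.01. Of 41 members named on the array, 11 passed the detection filter and were measured. A member undetected in control was kept only if detected on all VPA arrays, which favours rises among such members. Of the 11 measured, Bex4 (4.18-fold) and the ubiquitin hydrolase Uchl1 (3.40-fold) rose, 4 genes when adjusted over the list alone. The list's call was also lost without VPA replicate 2 (0.0512), with median scaling (0.0639) and without a detection filter (0.315), over a range of 0.00129 to 0.315. Of 29 histone deacetylases and acetyltransferases, the enzyme class VPA inhibits and its counterpart, 0 passed over all genes or over the list alone, and 1 was higher and 3 lower at an unadjusted p under 0.05. Hdac10 had a log2 change of -0.84 ± 0.31 (adjusted p = 0.230), or -0.48 without VPA replicate 1, and Hdac11 one of 0.76 ± 0.22 (0.139), and the list an adjusted p of 0.119 by camera. By fry the list was lower (adjusted p = 0.0326). Of 24 histone genes the linker histone H1f10 (2.01-fold) rose, 1 gene also when adjusted over the list alone. The list's median of 0.005 and mean of 0.01 lay above 0 and its test pointed downward (0.988).

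Of 34 genes of cytokine signalling through JAK and STAT, the early growth response gene Egr1 (2.51-fold), the receptor chain Csf2rb2 (2.29-fold), Id1 (2.02-fold) and the interleukin 3 receptor chain Il3ra (1.66-fold) rose, and 7 rose and 1 fell when adjusted over the list alone (list adjusted p = 0.0614, or adjusted p = 0.278 with an estimated correlation). Without a detection filter the list passed (0.0384), over a range of 0.0384 to 0.278 by camera. Of 13 Wnt targets and components 0 passed over all genes, 4 were higher at an unadjusted p under 0.05 and 2 rose when adjusted over the list alone. Tcf7l1, detected on 0 of the control arrays, was at least 1.57-fold higher without passing (adjusted p = 0.0735 by limma), Tle2 had a log2 change of 0.75 ± 0.18, and the list an adjusted p of 0.0567, or 0.0484 without VPA replicate 1 and 0.0375 without control replicate 1, over a range of 0.0375 to 0.278 by camera. With VPA replicate 1 left out of the normalization too it was 0.0740, and without that array 0.334 with an estimated correlation. Of 23 genes of antigen presentation the protease gene Ctsh (2.24-fold) rose, 3 genes when adjusted over the list alone (list 0.283). Of 23 interferon response genes 0 passed over all genes or over the list alone, and 2 were higher and 1 lower at an unadjusted p under 0.05, Rsad2 among the former at 0.78 ± 0.18. Ifi47, at -0.57 ± 0.30, or -0.21 without VPA replicate 1, was not past that value (list 0.804). Of 19 genes of fatty acid oxidation and PPAR targets, chosen because VPA is itself a fatty acid, 0 passed over all genes or over the list alone and 2 were higher at an unadjusted p under 0.05, Acot1 among them at 0.84 ± 0.20. Acaa2, at -0.58 ± 0.62, was not past that value (list 0.119). Without VPA replicate 1 the value of Acaa2 was positive (0.25 ± 0.13). The calls of the 22 list members past the threshold held in all alternatives for 6 and ended in at least 1 for 16, with adjusted p up to 0.213 (Il3ra). The sample check gave Xist at 11.55 ± 0.30 (SD) in control and 11.26 ± 0.35 in VPA arrays on the normalized log2 scale, and Uty at 6.38 ± 0.58 and 5.97 ± 0.92.

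**Figure D3:**
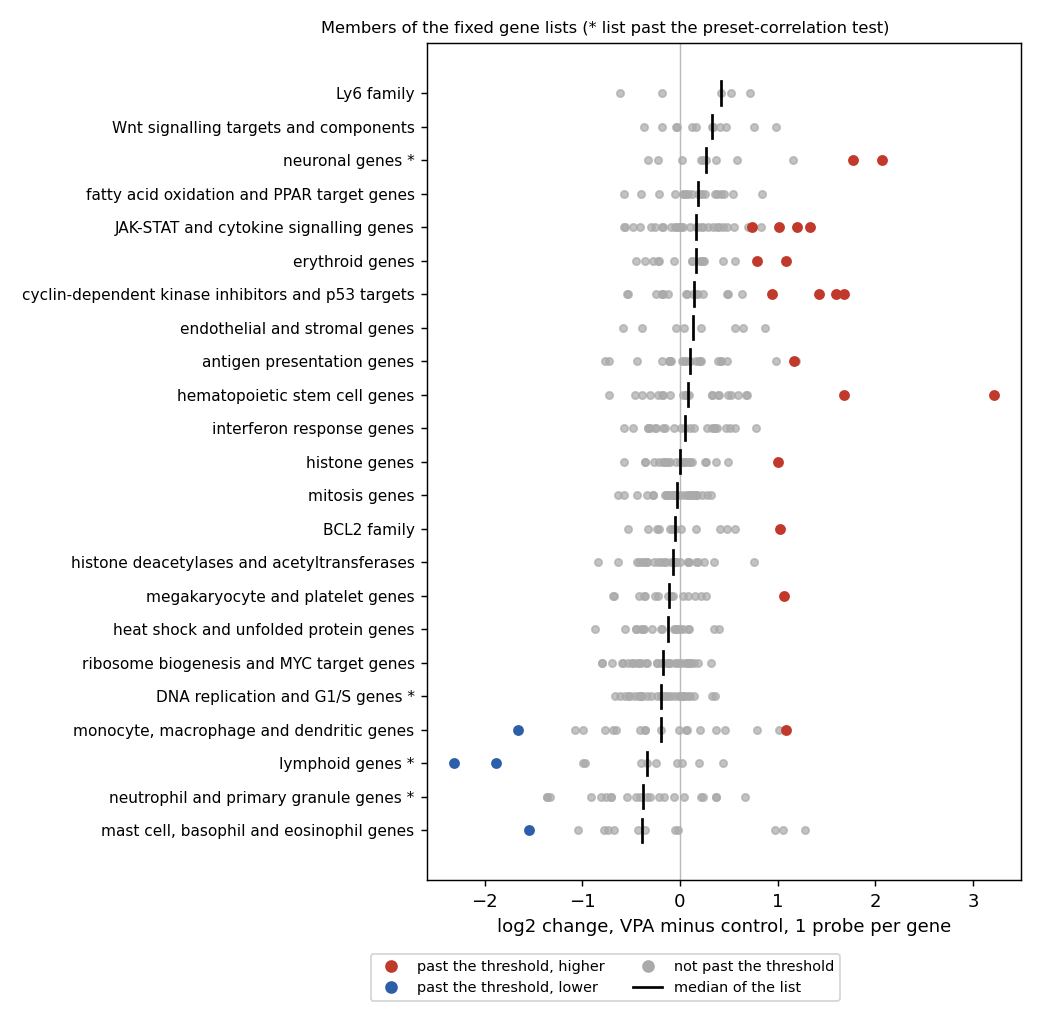
Log2 change with VPA of each measured member of the 23 tested gene lists, 1 point per gene shown by its brightest probe, red for genes past the threshold upward, blue downward and grey for the others; black ticks mark list medians and asterisks the 4 lists past the preset-correlation test. The lowest value among the lymphoid genes is that of Dntt, at -2.31, and the highest among the stem cell genes that of Thy1, at 3.21.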

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

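Of the alternatives below, 2 were chosen after seeing the data, the normalization of 5 arrays without VPA replicate 1 and the Actb covariate. The comparison gave 272 genes higher and 25 lower, and 1 list upward and 3 downward. Median scaling gave 176 genes higher, array weights 1365 higher and 1128 lower, the 5-array normalization 104 lower and the Actb covariate 156 higher and 12 lower. The stricter adjusted p of 0.01 left 77 higher and 6 lower, and a 2-fold minimum 15 lower, by construction. With each array left out in turn the genes ranged from 54 to 494 higher and from 5 to 127 lower, and the lists from 0 to 4 upward and from 1 to 3 downward. The array weights ran from 0.0904 for VPA replicate 1 to 13 for VPA replicate 2, so their counts rest largely on that array, and the fit of the weights did not converge. For the other counts the cause was not tested. No value could be given for Ly6a, which was not analysed here.

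Lists numbered 0 upward and 1 downward with median scaling, 2 upward with the stricter detection filter, 2 upward and 0 downward with array weights, 0 downward with the 5-array normalization and 1 downward with the mean of a gene's probes. Camera with an estimated correlation gave 0 upward and 0 downward, and fry, which does not compare a list with other genes, 5 upward and 2 downward. The 2 were the lymphoid list and that of histone deacetylases and acetyltransferases.

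With a replicate block 178 genes were higher and 13 lower. Deviations from the group means correlated between same-numbered arrays at 0.128, -0.0564 and 0.0521. Between arrays of unlike number the values ran from -0.113 to 0.150. No pairing by number was seen, though so few values cannot exclude a weak one.

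In p-values of limma's camera the BCL2 list turned downward with median scaling (unadjusted value 0.995), the stricter detection filter (0.638), without VPA replicate 1 (0.976) and with the 5-array normalization (0.597), and with single arrays left out its p ranged from 0.621 to 0.976. In p-values of camera, or fry where named, the histone list turned upward with median scaling (unadjusted value 0.224), no detection filter (0.989), array weights (0.722), the replicate block (0.946), the 5-array normalization (0.736), the mean of probes (0.615) and fry (0.607), and without control replicate 1 (0.598) or VPA replicate 1 (0.816), over a range of 0.598 to 0.928 with single arrays left out. Acaa2 turned positive with array weights (0.18), without VPA replicate 1 (0.25) and with the 5-array normalization (0.25), and so did Uty (0.19, 0.11 and 0.12). With single arrays left out their log2 changes ranged from -1.02 to 0.25 and from -0.75 to 0.11. The cause was not tested. Neither list nor gene passed its threshold in any of these. Of the other comparisons of a named gene with its alternative, 990 kept direction and side of the threshold, 154 lost the call and 33 gained one; for lists these were 378, 26 and 19. Signal over background limits all of this on VPA replicate 1, at 2.46 against at least 4.25 elsewhere.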

Other observations

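Tests chosen only after the result was seen were those of the gene families, the neighbouring genes, the stronger response, the noise of dim probes, the share of rises without VPA replicate 1 and the Actb probes. The tests of the families, of the Actb probes and of quantile normalization took the form given here after a first form had been run. The families and neighbouring genes were picked by reading the genes past the threshold, so the family tests, run on members already seen to rise, do not show that a family rises more often than other genes. The genes in the next 2 paragraphs were singled out after their values were seen.

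Core proteins of heparan sulphate proteoglycans were higher with VPA in 6 of 7 measured genes, with 0 lower by limma, also at an unadjusted p under 0.05. After Gpc3, the largest were Col18a1 at 5.45-fold (log2 change 2.45 ± 0.17 SE, n = 3 per group), agrin (Agrn) at 4.57-fold and Gpc1 at 4.10-fold, followed by the syndecan genes Sdc3 at 2.82-fold and Sdc2 at 2.15-fold, while Gpc2 did not pass (0.23 ± 0.50, with a range of -0.20 to 0.86 over the alternatives). The 6 genes had a positive log2 change in all 18 alternatives, though Gpc1 and Sdc3 passed the threshold in 15 of them and Sdc2 in 13. Of the 3 members outside the 40 probes with the largest rises and the 40 with the largest falls 2 rose against 2.95% of other genes, a one-sided Fisher exact p of 0.00259, or 1.02e-08 with all 7 members, as first run. Of 15 glutathione transferase genes, which conjugate glutathione to reactive compounds, 5 rose by limma and 0 fell, also at an unadjusted p under 0.05, among them Gsta4 at 5.29-fold, Gstt1 at 4.51-fold, Gstm5 at 2.53-fold and Mgst3 at 1.89-fold, and 8 rose without VPA replicate 1. Among the 13 members outside the largest changes 3 rose, a one-sided Fisher exact p of 0.00596, or 0.000101 with all 15, as first run. The calls of these 3 often ended, with Gstm5 and Gstk1 past the threshold in 12 of 18 alternatives and Mgst3 in 11. Of 9 Bex and Tceal genes Bex4 and Tceal5 rose and Bex6 fell. Of the 5 members outside the largest changes 0 rose by limma and 2 were higher at an unadjusted p under 0.05. The one-sided Fisher exact p was 1, or 0.0357 with all 9 members, as first run, and none of these family tests decides.

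Of further genes, Cox6b2 rose 3.33-fold and Cox7a1 was 1.93-fold lower (adjusted p = 0.0315 by limma), past the threshold in 18 and 7 of 18 alternatives. No test was run of the cytochrome c oxidase genes as a group. Slc22a18 (2.64-fold) and Phlda2 (2.18-fold), which with Cdkn1c neighbour each other, rose and passed in 7, 12 and, for Cdkn1c, 11 of 18 alternatives. Ang and Rnase4, another neighbouring pair, were at least 2.42-fold and at least 3.39-fold higher. Whether neighbours rose together more often than in permuted calls was not decided. Among 7706 pairs of neighbouring measured genes of unlike names 13 rose together against a median of 9 in 10000 permutations (one-sided permutation p = 0.115).

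VPA replicate 1 stood apart from the other VPA arrays. Across all genes VPA replicate 1 minus VPA replicate 3 correlated with VPA replicate 2 minus control at r = 0.115. Most of these genes were not called, so this cannot decide on a stronger response of the genes that responded. Of the 621 genes called without this array, 554 lay on the same side of control in it. Over the 621, its difference from control correlated with that of VPA replicates 2 and 3 at r = 0.822, against 0.506 over all genes. The 621 were picked by VPA replicates 2 and 3, and both differences share the control mean, which favours a high r. Neither the count nor r measures whether the response was larger. A stronger response of the same genes stays open. The tables argue against noise limited to dim probes. Among the 1992 brightest genes VPA replicate 3 differed from VPA replicate 2 with a log2 SD of 0.17. VPA replicate 1 did so with 0.50, or 2.94 times that. Whether the transcript make-up of that culture differed was not decided. The deviation of VPA replicate 1 correlated between 2 probes of a gene at r = 0.109 over 1924 genes, or 0.177 where the second probe was bright. For the difference of VPA replicates 2 and 3 from control, a contrast of group means, r was 0.685. For control replicate 3 minus control replicate 1, a contrast of single arrays, it was 0.241. The 2 probes of a gene thus shared little of the deviation. Noise of single probes on this array would lower r even if the make-up had changed, so the test cannot exclude such a change. Differences at the level of single probes, in labelling or RNA quality, may give such a low value and stay open, with no separate measure of RNA quality used here.

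More genes rose than fell, 272 against 25, or 91.6% of the calls, while 920 were higher and 445 lower at an unadjusted p under 0.05, and 1328 higher and 891 lower among genes whose groups did not overlap (10% of genes by chance). A detection floor that hides falls is argued against by genes brighter than the median, where 50 rose and 3 fell (94.3%), and quantile normalization by a share of 91.2% with median scaling. VPA replicate 1 as the whole cause is argued against by a share of 79.5% without it, though the share moved. With array weights, which rest largely on VPA replicate 2, the share was 54.8%, so the excess may come in part from how the arrays are weighted. That an inhibitor of histone deacetylases raises more transcripts than it lowers stays open as a hypothesis.

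Probes of Actb, the beta-actin gene with 5 kept probes, disagreed between arrays. Of all pairs among the 5, the pair whose difference varied most over the controls was taken, so it shows the widest disagreement there. The log2 difference of these 2 probes was -0.66, 1.55 and 3.16 in the controls and 1.20, 3.31 and 2.84 with VPA. Across genes control replicate 3 minus control replicate 1 correlated with the VPA mean minus control replicate 2 at r = 0.0910. That argues against such an axis as the whole cause of the group difference. The VPA mean includes VPA replicate 1, at 1.20, so a contribution of the axis is not excluded. With the Actb difference as a covariate 156 genes were higher and 12 lower, including 151 of the 272 and 10 of the 25. What parts these probes stays open, and their positions in the transcript were not used here.

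The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For genes past the threshold by limma the real split gave 297 and the highest of the others 0. At an unadjusted p under 0.05 these were 1365 and 313. For lists the real split gave 4 and the highest of the others 2. In both, the 1 split of the 10 that reached the real value was the real split itself.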
